A study of Mus musculus with 14 samples.

How the data were processed

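The samples were EDL and soleus muscles of Ts1Cje mice and WT littermates, with 3 arrays per genotype for the EDL and 4 for the soleus. Per the labels, 25 ng of RNA per sample was labelled with Cy3 and hybridised to 1-colour Agilent arrays. The authors scanned the slides and extracted the spots with Agilent Feature Extraction, version 11.5.1.1 per the file headers and 9.1 per the submitters' notes, a difference that stays open. The deposited scanner files hold gProcessedSignal, an intensity with the background subtracted and spatial trends removed and with no normalization between arrays. They also hold, per the file headers, the median intensity of each spot and of its background, and other columns of 0 or 1 that mark spots as saturated, as outliers or as well above background. The authors' deposited table of normalized values is in log2 units, scaled to the 75th percentile of each array and centred on the median of each probe over the 14 arrays. The lowest correlation of that table with the same values computed from the scanner files was 0.9999. Probe positions are those of the mm9 build named in the file headers, and no reference genome was used.

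Each array held 62976 spots, of which 3671 were controls. The 59305 other spots measured 55681 probes, and spots of 1 probe were averaged, leaving out outlier spots where others remained. Of the probes, 33822 had a symbol, 31833 were named through the reference, 2172 symbols were updated, and 21839 stayed unnamed and were counted apart. Values were log2 of gProcessedSignal minus the log2 75th percentile of each array. A probe was kept if well above background on every array of at least 1 of the 4 groups, which kept 25182 probes, 18517 with a symbol and 6665 without. A gene was represented by its kept probe with the highest mean, which gave 14170 genes, 3558 of them with more than 1 kept probe.

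With R 4.3.3, limma 3.58.1 fitted 1 mean per group to all 14 arrays, with 10 residual and 2.789 prior degrees of freedom. The contrasts were Ts1Cje minus WT in the EDL and in the soleus, the difference and the mean of these effects, and EDL minus soleus in WT and in Ts1Cje. Tests were two-sided with Benjamini-Hochberg adjustment over the genes, and a gene was called, written as rose or fell, at an adjusted p under 0.05. The median SE of a log2 change was 0.18 in the EDL, 0.16 in the soleus, 0.24 for their difference, 0.12 for their mean and 0.17 between muscles. Where no probe of a gene was well above background on any array of 1 group, the fold is a bound, computed against the larger of the signal and the lowest signal of any probe well above background on each array. Setting such genes at their bounds moved 0 list medians.

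Before the data were examined, the comparisons, the tests, the alternatives and 36 gene lists from general knowledge were fixed, of which 35 with at least 3 measured genes were tested. Each list was tested with limma camera, with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison, and with fry beside it. Camera compares a list with the other genes, and its adjusted p is given here for the preset correlation unless stated otherwise. Called lists numbered 5 in the EDL, 6 in the soleus, 5 for the difference, 7 for the mean, and 9 in each muscle comparison. With an estimated correlation they numbered 1, 1, 0, 1, 1 and 2 in the same order. The other lists had an adjusted p of at least 0.0568 in the EDL, 0.0873 in the soleus, 0.15 for the difference, 0.133 for the mean, 0.218 in WT and 0.122 in Ts1Cje. Differences in list means per array were tested with exact permutation tests, two-sided, which cannot go below p = 0.1 with 3 against 3 arrays. List sources overlap in a few genes, such as Cd36 in the slow fibre and fatty acid oxidation lists and Pfkm, Gpd1 and Pgam2 in the fast fibre and glycolysis lists.

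The rule for named genes took, per comparison, the 10 called genes that rose most and the 10 that fell most (the 5 of smallest p where fewer than 5 were called in a direction), the 6 trisomic genes of smallest p, 15 fixed genes, and up to 4 called members of each list. Names of clones were passed over. The rule gave 334 gene and comparison pairs, of which 227 are printed. In the genotype comparisons, their difference and their mean, all genes of the rule are printed. The 107 left out are called genes in the muscle comparisons, nearly all of them list members, and which to leave out was chosen after the values were seen. Lists printed beside the called ones were also chosen after the values were seen.

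On simulated data of the same size, limma recovered in the soleus 34.3% of 1.5-fold, 80.6% of 2-fold and 98.5% of 4-fold changes, with 8 false calls of 150, and in the EDL 8 false calls of 137. A simulated shift of the trisomic list was called by camera in all 6 comparisons. In the simulated EDL data 3 lists were called, of which 2 were false, and in the other 5 comparisons 1 list each was called.

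Arrays of the same replicate number were checked for pairing by correlating their deviations from group means. EDL Ts1Cje and EDL WT gave 0.40, 0.12 and 0.31, and EDL WT and soleus WT 0.51, 0.41 and 0.33, all over 0.1. These pairs were left out of the main fits. The labels do not say that a number marks a litter or an animal. Slide and scan were the same division of the arrays.

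The alternatives were background correction by normexp (offset 50) on spot and background medians with quantile normalization, quantile normalization alone, centring on medians, the authors' normalized values, no filter, probes well above background on all arrays, the mean of all probes of a gene, a minimum of 1.5-fold, the muscles or genotypes fitted alone, the replicate number, the slide and the slide row as blocks, array weights, a trended robust variance and leaving out each array in turn. The normexp correction had been planned on spot means, which the files do not hold. The settings chosen after the data were seen were the Ts1Cje arrays of slide 1 alone, the soleus arrays of slide 2 alone and the segment taken by probe position. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The comparisons left out 0 value columns of the deposited table.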

Results

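Gene expression was measured in 14 skeletal muscle samples of mice, with 1 Agilent 1-colour microarray per sample. Ts1Cje is a mouse model of Down syndrome that carries an extra copy of a distal segment of chromosome 16, and disomic littermates on the C57BL/6 background (WT) were the controls. The samples came from the EDL (extensor digitorum longus), a fast-twitch muscle of the hind limb, with 3 arrays per genotype, and from the soleus, a slow-twitch muscle, with 4 arrays per genotype. Between 41.3% and 52.9% of the 55681 probes were well above background on an array, the 75th percentile of the signal lay between 68.7 and 159 intensity units, and 0 probes were saturated. Across genes, arrays of the same group had Pearson correlations between 0.979 and 0.988. The number of arrays limits the precision, and the p-values measure the spread between samples. The first principal component held 53.9% of the variance and separated the muscles, with EDL arrays between -52.8 and -37.3 and soleus arrays between 24.6 and 41.9. Slide 1 held the 6 EDL arrays and soleus Ts1Cje replicate 1, and slide 2 held the other 7 soleus arrays.

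The first comparison asked which genes differ between Ts1Cje and WT in the EDL. As a group, genes of the trisomic segment were higher in Ts1Cje, by a median of 1.44-fold (log2 0.53, interquartile range 0.40 to 0.62), with 50 of 53 measured members higher, beside a log2 of 0.58 for 3 copies over 2. Dnah11, which encodes a dynein heavy chain of motile cilia, rose at least 103-fold, or by log2 4.45 with normexp background correction (offset 50), and was the 1 gene called among 14170 (limma adjusted p = 5.69e-07, n = 3 and 3). Its probe, on chromosome 12 from 119116456 to 119116515 (mm9), was well above background on 7 of 7 Ts1Cje arrays of both muscles and on 0 of 7 WT arrays. Sod1, the cytosolic superoxide dismutase, stood at 1.82-fold (log2 0.86 ± 0.14 SE, limma adjusted p = 0.101), short of the threshold, and was called with normexp, quantile normalization or a trended robust variance (adjusted p from 0.00156 to 0.0424).

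In the trisomic segment list, 0 members were called in the EDL over all genes and 32 were higher when adjusted over the list alone, and the list as a whole was called (limma camera adjusted p = 1.58e-54, and 7.22e-07 with an estimated correlation). Tmem50b had the smallest p of its members, at log2 0.78 ± 0.11 (SE, limma adjusted p = 0.0913), and was called with normexp, array weights or a trended robust variance (adjusted p from 0.021 to 0.0478). Gart, an enzyme of purine synthesis, stood at log2 0.56, Ifnar1, a chain of the type I interferon receptor, at 0.48, and Psmg1, a proteasome assembly chaperone, at 0.58. Also not called were Pigp, of glycosylphosphatidylinositol anchor synthesis, at 0.53, and Vps26c, of endosomal sorting, at 0.57. The kinase gene Dyrk1a stood at log2 0.83, the transcription factor gene Runx1 at 0.73, and Rcan1, an inhibitor of calcineurin, at 0.60 ± 0.37 (SE), none of them called. The control list of 30 genes elsewhere on chromosome 16 had a median log2 change of 0.06 (camera adjusted p = 0.714), with 0 members called over all genes and 0 over the list alone. Of the genes of the small chromosome 12 deletion, 3 were measured, and their median was -0.18, 0.06 without Ts1Cje replicate 2. Their mean and the direction of camera were upward because of Dnah11 (adjusted p = 0.0568), the 1 member called, over all genes and over the list alone. That list was called under quantile normalization (adjusted p = 0.0201, and adjusted p = 0.253 with an estimated correlation) and with normexp (adjusted p = 0.000612, and 0.0384). It was also called without WT replicate 1 or Ts1Cje replicate 3 (adjusted p = 0.0213 and 0.0421, and 0.31 and 0.491 with an estimated correlation).

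Of the other lists, 4 were called upward in the EDL by camera with the preset correlation, all with 0 members called over all genes and 0 over the list alone. Interferon-stimulated genes had a median log2 change of 0.19, with 30 of 35 higher (adjusted p = 1.17e-06, and 0.704 with an estimated correlation). Genes of the extracellular matrix had a median of 0.16, with 23 of 25 higher (adjusted p = 0.0105, and 0.712 with an estimated correlation). Macrophage markers had a median of 0.20, with 10 of 11 higher (adjusted p = 0.0105, and 0.671 with an estimated correlation). Heat shock genes had a median of 0.13, with 14 of 15 higher (adjusted p = 0.0239, and 0.705 with an estimated correlation). The interferon call was lost without Ts1Cje replicate 2 (median 0.11, adjusted p = 0.107), and the median was 0.43 without Ts1Cje replicate 1 and 0.11 with normexp. The matrix call was lost without WT replicate 1 or Ts1Cje replicate 1 or 2 (adjusted p from 0.0901 to 0.573). Without WT replicate 3 the matrix and macrophage medians were 0.27 and 0.39, and without Ts1Cje replicate 3 the matrix median was 0.245. The macrophage and heat shock calls were lost in 4 each of 6 fits without single arrays (adjusted p from 0.0615 to 0.15 and from 0.0755 to 0.556), and the heat shock call with quantile normalization or array weights (adjusted p = 0.0692 and 0.0736). Neutrophil markers (median -0.53, 3 measured) and red blood cell markers (median -0.28, 8 measured) were not called (adjusted p = 0.148 and 0.116), and with the pairs as a block they were (adjusted p = 0.0423 and 0.0102). With an estimated correlation and no block, those lists had an adjusted p = 0.671 and 0.738, and with the block adjusted p = 0.699 each. The red blood cell list was called downward without WT replicate 1, Ts1Cje replicate 1 or WT replicate 2 (medians -0.365, -0.51 and -0.61, adjusted p = 0.0417, 0.00814 and 0.000195), and not with an estimated correlation (adjusted p from 0.482 to 0.676). Its median was 0.10 without Ts1Cje replicate 2, 0.12 without WT replicate 3 and -0.43 without Ts1Cje replicate 3, where it was not called (adjusted p = 0.888, 0.454 and 0.089). Without Ts1Cje replicate 3 the heat shock median was 0.02 and the neutrophil median -0.11.

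In the EDL no contractile gene named here was called. Myh4, the fast myosin heavy chain IIb, stood at log2 0.04 ± 0.62 (SE) and Pvalb, the calcium buffer parvalbumin of fast fibres, at 0.04 ± 0.24, and both turn to -0.04 under quantile normalization. The fast fibre list had a median of 0.04 (14 of 21 higher, camera adjusted p = 0.744), which turns to -0.02 under quantile normalization. The slow fibre list had a median of -0.29 (12 of 18 lower, camera adjusted p = 0.339). It was called downward without WT replicate 2 (-0.98, adjusted p = 1.34e-08), without Ts1Cje replicate 3 (-0.91, adjusted p = 5.04e-06) and with array weights (-0.72, adjusted p = 0.00228), and in none of these with an estimated correlation (adjusted p from 0.482 to 0.713). Its median was 0.02 without Ts1Cje replicate 2, 0.01 without WT replicate 1, -0.10 without Ts1Cje replicate 1 and -0.06 without WT replicate 3, where it was not called. Myh7, the slow myosin heavy chain, varied within the groups, from log2 -0.16 to 6.30 over the WT arrays and from 2.23 to 5.50 over the Ts1Cje arrays, with a difference of -0.35 ± 1.28 (SE) that turns to 0.85 without WT replicate 1. The slow troponin gene Tnnt1 stood at log2 -0.74, Myh2 at 0.135, Myh1 at 0.07, Tnnt3 at -0.01 and Atp2a1 at 0.01. App stood at 0.08, Itsn1 at 0.03 and Ppargc1a, a coactivator of mitochondrial genes, at 0.01. None of these 8 was called, and all but Tnnt1 change direction under other settings or without single arrays. The genes of smallest p beside those above were Rab32, a small GTPase of vesicle traffic (log2 0.95, adjusted p = 0.101), Dppa5a (0.85), Zcchc3 (-1.05), Xpo4, an exportin (-0.76), Atp6v1e2, a proton pump subunit (-0.79), and Csk, a kinase that restrains Src (-0.63), none of them called. Rab32 was called with array weights or without WT replicate 3 (adjusted p = 0.0491 and 0.047). Mup19, a major urinary protein, was at least 2.85-fold lower in Ts1Cje (adjusted p = 0.602, not called, and log2 -0.60 with normexp). At unadjusted p under 0.05 there were 411 genes (630 with the EDL alone, paired), beside 708.5 by chance. Of simulated changes limma recovered 23.9% at 1.5-fold and 73.1% at 2-fold. These rates may be too high, as 0 of 53 trisomic genes (median 1.44-fold) were called. The count of 1 was 0 to 3 in other settings, 2 without WT replicate 1 or 2 or Ts1Cje replicate 3, and 4 without WT replicate 3.

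**Figure D1:**
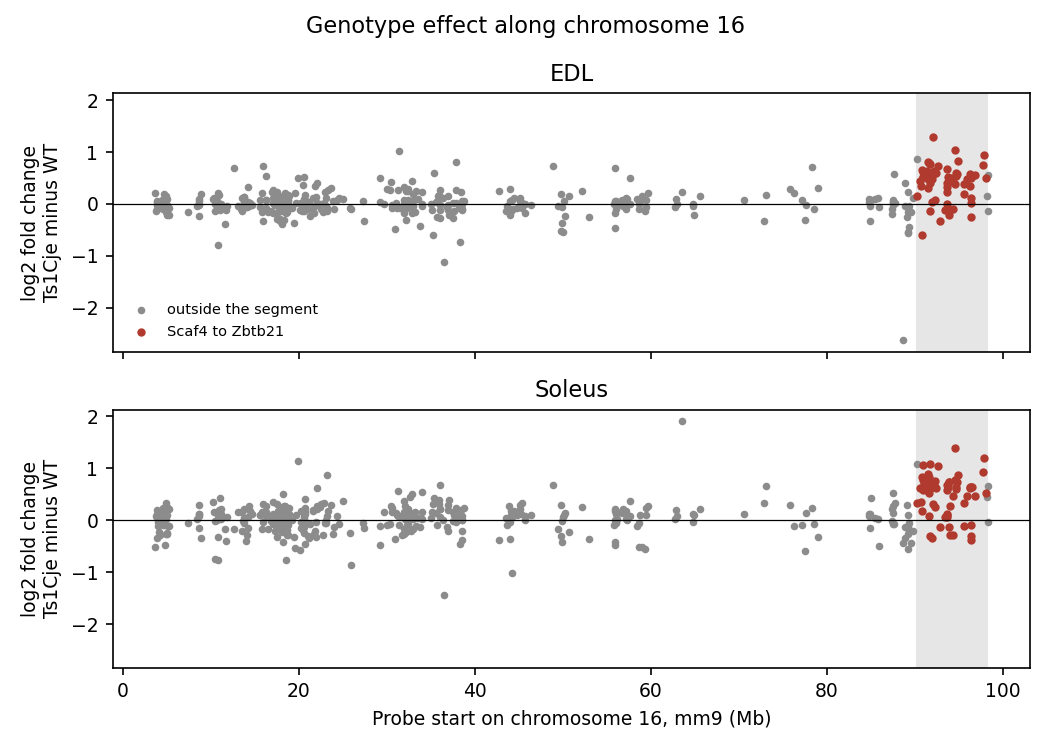
Log2 change in Ts1Cje over WT of each measured gene on chromosome 16 by its probe position (mm9), in the EDL and in the soleus. The grey band marks the trisomic segment, where the median change of the 64 genes was 0.50 in the EDL and 0.61 in the soleus.

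The second comparison asked the same of the soleus. Of 21 measured genes of fast-twitch fibres 3 fell in Ts1Cje, while the list had a median of -0.16 (camera adjusted p = 1.94e-07, and adjusted p = 0.351 with an estimated correlation). Myh4 fell by 4.14 ± 0.53 on the log2 scale (SE, 17.6-fold), from 9.26 ± 0.47 (SD, n = 4) in WT to 5.13 ± 1.42 (SD, n = 4). Pvalb fell by 1.88 ± 0.21 (SE, 3.67-fold), and Actn3, the fast-fibre actin crosslinker alpha-actinin-3, fell by 1.96 ± 0.28 (SE, 3.89-fold), a call lost without WT replicate 1, Ts1Cje replicate 2 or WT replicate 3 (adjusted p from 0.0525 to 0.0626). Genes of the trisomic segment were higher by a median of 1.55-fold (log2 0.63, interquartile range 0.35 to 0.74), with 47 of 53 members higher. Sod1 rose 2.11-fold (log2 1.08 ± 0.12 SE), and Dnah11 rose at least 151-fold (log2 4.87 with normexp). In all, 34 of 14170 genes were called (limma), of which 24 rose and 10 fell, and 1837 had an unadjusted p under 0.05, beside 708.5 for evenly spread p-values and up to 2002 in other groupings of the same arrays.

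Of the trisomic list, 18 members rose in the soleus and 0 fell over all genes, and 38 rose and 1 fell over the list alone. The list made up 52.9% of the calls and 0.374% of the genes tested (Fisher's exact test, two-sided, p = 1.67e-36), and camera called it (adjusted p = 1.86e-26, and 2.32e-05 with an estimated correlation). Tmem50b rose by log2 0.84 ± 0.10 (SE, limma adjusted p = 0.00486), Morc3, a nuclear matrix ATPase, by 0.73 (0.475 with normexp, adjusted p = 0.00554), Son, a splicing cofactor, by 0.65 (adjusted p = 0.00752), and Synj1, a phosphoinositide phosphatase of synaptic vesicle recycling, by 0.77 (adjusted p = 0.00776). Runx1 rose by log2 1.04, Eva1c by 1.07, Ifnar2, the other chain of the type I interferon receptor, by 0.82, Smim11 by 0.75, Dop1b by 0.74 and Vps26c by 0.74, with adjusted p from 0.0116 to 0.0421. Over 8 fits without single arrays the calls of Eva1c and Smim11 were lost in 7 each, those of Runx1 and Ifnar2 in 6 each, that of Dop1b in 3 and that of Vps26c in 2 (adjusted p from 0.0506 to 0.161), and those of Sod1, Dnah11, Tmem50b, Morc3, Son and Synj1 in 0. Dyrk1a (log2 0.88, adjusted p = 0.181) and Rcan1 (0.63, adjusted p = 0.416) were not called, nor was Itsn1, an endocytic scaffold, at -0.34 (adjusted p = 0.498), which turns to 0.33 with the mean of its probes, since 1 of its 5 probes goes that way. Members lower in both muscles numbered 2. By position, 64 measured genes had their probe in the segment (90229636 to 98168748, mm9), and the Sod1 probe lies before it (90226509 to 90226568). Of the 64, 19 were called in the soleus and 0 in the EDL, with medians of 0.61 and 0.50. The control list elsewhere on chromosome 16 had a median of 0.10 (camera adjusted p = 0.454), beside 0.06 for all soleus genes. That shift raises list means and counts of higher members. The control mean per array was higher on 4 of 4 Ts1Cje arrays than on any WT array (-0.041 against -0.046, exact p = 0.0286). App, the amyloid precursor gene of that list, stood at 0.42 (adjusted p = 0.291). The chromosome 12 deletion list had a median of -0.20 (0.10 without Ts1Cje replicate 1), while its mean and the direction of camera were upward because of Dnah11 (adjusted p = 0.432), and over the list alone 1 member rose and 1 fell.

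**Figure D2:**
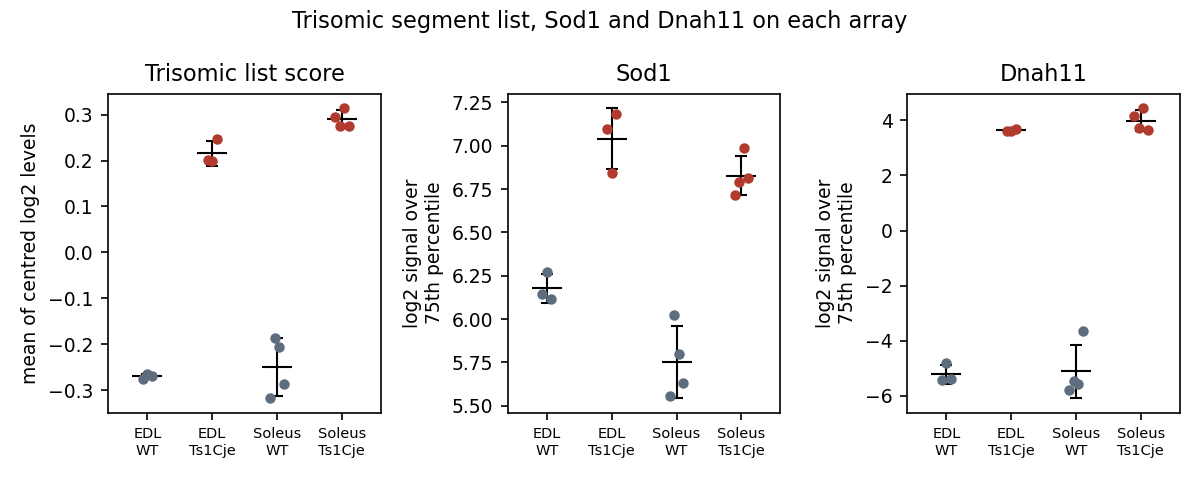
Mean of the centred log2 levels of the trisomic list, and log2 signal over the 75th percentile of Sod1 and of Dnah11, on each array (points) with the mean (horizontal bar) and SD (error bars) of the 3 EDL or 4 soleus arrays of a genotype. The list lies between 0.20 and 0.31 on the Ts1Cje arrays and between -0.32 and -0.19 on the WT arrays.

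Of the fast fibre list, 3 of 21 members fell in the soleus and 0 rose over all genes, and 4 fell over the list alone. The list had a mean log2 change of -0.56, with 18 members lower. Its difference was also seen with the slide as a block (adjusted p = 3.43e-07) and within slide 2 (median -0.19, adjusted p = 1.16e-06, and adjusted p = 0.705 with an estimated correlation). Averaged per array, the list was lower in 4 of 4 Ts1Cje arrays than in any WT array (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 allow, and 0.167 adjusted over the lists). The same p was reached by 6 of 35 lists, the others being slow fibres, red blood cells, the trisomic segment, the chromosome 12 deletion and the chromosome 16 control. The fast fibre median was -0.10 without WT replicate 2. The fast calcium pump Atp2a1 stood at log2 -0.59 (adjusted p = 0.334), and Myh1 and Myh2, fast myosin heavy chains IIx and IIa, at -0.12 and -0.09, where Myh2 turns to 0.00 under quantile normalization and Myh1 to 0.04 without WT replicate 2. The slow fibre list had 18 of 18 members higher by a median of 0.21 and was not called (camera adjusted p = 0.406), with 0 members called over all genes and 0 over the list alone, and Myh7 stood at 0.17 (adjusted p = 0.96). The slow fibre list was called upward within slide 2 (median 0.24, adjusted p = 0.0228), with the soleus fitted alone (adjusted p = 0.00582) and without the filter (adjusted p = 0.049), and in none of these with an estimated correlation (adjusted p from 0.57 to 0.785). With the slide as a block over all soleus arrays it was not called (0.24, adjusted p = 0.478). Red blood cell markers were higher by a median of 0.42 (8 of 8) and neutrophil markers lower by a median of -0.31 (3 of 3). Neither list was called (camera adjusted p = 0.136 and 0.0873, and 0.781 and 0.474 with an estimated correlation), with 0 members called over all genes and 0 over the list alone. Within slide 2 both were called (0.33, adjusted p = 0.0184, and -0.36, adjusted p = 0.0328), but not with an estimated correlation (adjusted p = 0.785 and 0.705) or with the slide as a block, which gave the same medians (adjusted p = 0.457 and 0.0884). The red blood cell list was also called with the soleus fitted alone (adjusted p = 0.000375) and without Ts1Cje replicate 3 (adjusted p = 0.0178), and the neutrophil list with normexp (adjusted p = 0.0451) and without WT replicate 4 (-0.685, adjusted p = 0.048). With an estimated correlation none of these calls was made (adjusted p from 0.24 to 0.644). The neutrophil median was -0.54 without WT replicate 1 and -0.595 without Ts1Cje replicate 3. Tnnt1 stood at 0.16, Ppargc1a at 0.08 and Tnnt3 at 0.01, none of them called, and the last 2 change direction without single arrays.

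**Figure D3:**
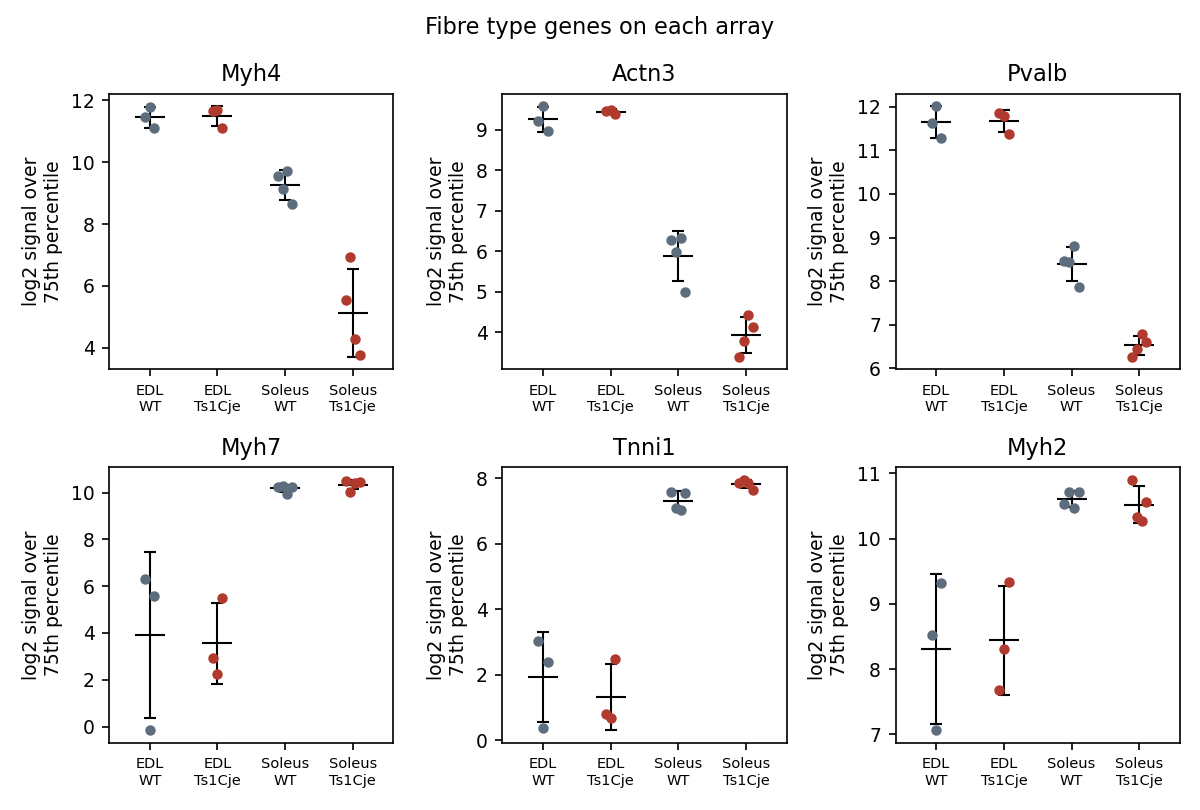
Log2 signal over the 75th percentile of Myh4, Actn3, Pvalb, Myh7, Tnni1 and Myh2 on each array (points), with the mean (horizontal bar) and SD (error bars) of the 3 EDL or 4 soleus arrays of a genotype. Myh4 lies between 8.65 and 9.71 on the WT soleus arrays and between 3.75 and 6.93 on the Ts1Cje soleus arrays.

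Genes of glycolysis had a median log2 change of -0.15 in the soleus, with 14 of 21 lower (camera adjusted p = 0.00557, and adjusted p = 0.675 with an estimated correlation). Genes of oxidative phosphorylation had a median of 0.10, with 58 of 68 higher (adjusted p = 0.00557, and 0.785 with an estimated correlation). Interferon-stimulated genes had a median of 0.35, with 32 of 35 higher (adjusted p = 7.08e-05, and 0.746 with an estimated correlation). With the slide as a block or without Ts1Cje replicate 1 that median was 0.23 and the call was lost (adjusted p = 0.101), with normexp the median was 0.21, and within slide 2 alone it was called (0.23, adjusted p = 0.0301, and adjusted p = 0.785 with an estimated correlation). Heat shock genes had a median of 0.18, with 15 of 15 higher (adjusted p = 0.0309, and 0.746 with an estimated correlation). Each of these 4 lists had 0 members called over all genes and 0 over the list alone. The glycolysis call was lost without WT replicate 3 or the filter (adjusted p = 0.124 and 0.0839), the oxidative phosphorylation call without WT replicate 1 (adjusted p = 0.166), and the heat shock call without Ts1Cje replicate 2 or WT replicate 3 or with the mean of probes (adjusted p = 0.31, 0.155 and 0.0513). The oxidative phosphorylation median was 0.06 without WT replicate 1 and 0.16 without WT replicate 2. The glycolysis median was -0.09 without WT replicate 1 and -0.07 without Ts1Cje replicate 4, and the heat shock median 0.11 without Ts1Cje replicate 2. Oxidative phosphorylation and heat shock also lost their calls under quantile normalization (adjusted p = 0.11 for each).

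Outside the trisomic list, 6 genes rose in the soleus and 10 fell. Ppp1r35, a centriole protein, rose by log2 1.01 (0.51 with normexp, limma adjusted p = 0.0179). Tbata fell by 1.66, Tlcd4 fell by 1.21, Pla2g1b, a secreted phospholipase, fell by 1.01, Apol7a fell by 0.99, and Nabp1, a protein that binds single-stranded DNA, fell by 0.85. Vmn2r111, a vomeronasal receptor gene, fell by 0.74, and the adjusted p of these 6 lay between 0.0166 and 0.0469. With normexp all 6 lost their calls (adjusted p from 0.228 to 0.787), as did Runx1 and Eva1c (adjusted p = 0.184 and 0.0826). The mean of probes ended the calls of Runx1, Dop1b, Tbata, Eva1c, Tlcd4 and Nabp1 (adjusted p from 0.0541 to 0.424). Over 8 fits without single arrays the call of Nabp1 was lost in 8, those of Tbata, Apol7a and Tlcd4 in 7 each, that of Vmn2r111 in 6, and those of Ppp1r35 and Pla2g1b in 5 each (adjusted p from 0.0508 to 0.16). Quantile normalization ended the calls of Tlcd4, Pla2g1b and Nabp1, and array weights and the authors' values that of Tlcd4 (adjusted p from 0.0509 to 0.158). A trended robust variance ended those of Eva1c, Runx1, Pla2g1b, Apol7a, Nabp1 and Vmn2r111 (adjusted p from 0.0775 to 0.228), and the slide row as a block those of Eva1c, Tbata and Tlcd4 (adjusted p from 0.0549 to 0.0628). The count of 34 was 18 with the slide as a block, where Pvalb (-1.79, adjusted p = 0.0135), Myh4 (-4.27, adjusted p = 0.0179), Actn3 (-1.78, adjusted p = 0.0405), Sod1 (1.11, adjusted p = 0.00907) and Tmem50b (0.90, adjusted p = 0.00907) were called. The slide block ended the calls of Runx1, Eva1c, Ifnar2, Smim11, Tbata, Nabp1, Tlcd4, Apol7a and Vmn2r111 (adjusted p from 0.052 to 0.123). In a fit of slide 2 alone (3 against 4 arrays) the adjusted p of Pvalb, Myh4, Actn3, Sod1 and Tmem50b lay between 0.0821 and 0.15. The count was 1 with the soleus fitted alone (Dnah11), 6 without the filter (Dnah11, Sod1, Tmem50b, Morc3, Myh4 and Pvalb) and 21 with the mean of probes. It was 18 without Ts1Cje replicate 1, 9 without WT replicate 1, Ts1Cje replicate 2 or Ts1Cje replicate 3, 14 without WT replicate 3 and 16 without WT replicate 4.

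The genotype effect in the EDL minus that in the soleus tests whether the muscles respond differently. No gene was called (limma, smallest adjusted p = 0.729), and 421 had an unadjusted p under 0.05 beside 708.5 by chance. Fast-fibre genes were among those of smallest p, with Pvalb at log2 1.91 ± 0.32 (SE, adjusted p = 0.729), Myh4 at 4.17 ± 0.81 (SE, adjusted p = 0.798) and Actn3 at 2.15 ± 0.43 (SE, adjusted p = 0.798). Pvalb was called with normexp (adjusted p = 0.0217) and Myh4 without soleus Ts1Cje replicate 2 (adjusted p = 0.0298). Nabp1 stood at 1.16, Pla2g1b at 1.14, Uevld at -1.09, Csk at -0.82, Ppp1r35 at -0.92, Gatd1 at -0.76 and Zcchc3 at -1.01, and Sod1 at -0.21 (adjusted p = 0.999). The trisomic genes of smallest p were Lca5l (0.43), Morc3 (-0.29), Dop1b (-0.32), Son (-0.25), Il10rb (-0.39) and Synj1 (-0.24). Atp2a1 stood at 0.595, Itsn1 at 0.36, Myh2 at 0.22 and Myh1 at 0.19. Tnnt1 stood at -0.91, Myh7 at -0.52, App at -0.34 and Runx1 at -0.32. Ppargc1a stood at -0.07, Dyrk1a at -0.05, Rcan1 at -0.03 and Tnnt3 at -0.02. Dop1b turns to 0.13 with the mean of its probes, and Myh2, Myh1, Myh7, Ppargc1a, Dyrk1a, Rcan1 and Tnnt3 change direction under other settings or without single arrays. In simulated data limma recovered 5.97% of 1.5-fold and 55.2% of 2-fold differences of this kind.

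As lists, the fast fibre genes had a higher genotype effect in the EDL than in the soleus (median log2 0.16, 19 of 21 higher, camera adjusted p = 5.23e-08, and adjusted p = 0.533 with an estimated correlation). No member was called over all genes, and 4 were higher over the list alone. Glycolysis genes differed in the same direction (median 0.13, 17 of 21 higher, adjusted p = 0.00271, and 0.845 with an estimated correlation). Genes of oxidative phosphorylation had a lower effect in the EDL (median -0.11, 61 of 68 lower, adjusted p = 0.00206), as did fatty acid oxidation (median -0.16, 26 of 29 lower, adjusted p = 0.0203) and red blood cell markers (median -0.70, 8 of 8 lower, adjusted p = 0.00675). For each of those 3 lists it was adjusted p = 0.942 with an estimated correlation, and the slide as a block ended the calls of the last 2 (adjusted p = 0.081 and 0.093). These 4 lists after the fast fibres had 0 members called over all genes and 0 over the list alone. With the replicate numbers as a block, which pair the genotypes in the EDL and not in the soleus, the fatty acid oxidation call was lost (adjusted p = 0.0552) and the slow fibre list was called downward (median -0.62, adjusted p = 0.0271). With no block the slow fibre list was not called (adjusted p = 0.15, and 0.942 with an estimated correlation), with 0 members called over all genes and 0 over the list alone. It was called without EDL WT replicate 2 or EDL Ts1Cje replicate 3 (adjusted p = 1.24e-08 and 6.56e-05), with array weights (adjusted p = 0.002) and without the filter (adjusted p = 0.0238). With an estimated correlation none of these calls was made (adjusted p from 0.531 to 0.998). Its median was -1.26 without either of those arrays and -0.0976, -0.20 and -0.22 without EDL Ts1Cje replicate 2, EDL WT replicate 1 or EDL WT replicate 3, where it was not called (adjusted p from 0.728 to 0.892). The trisomic list had a median of -0.07 and was not called (camera adjusted p = 0.87), with 15 of 53 members higher in the EDL effect, 0 of them called over all genes and 0 over the list alone. The oxidative phosphorylation call was lost without EDL replicate 2 of either genotype or soleus WT replicate 1 (adjusted p from 0.0669 to 0.355), and the glycolysis call without soleus WT replicate 3 or the filter (adjusted p = 0.063 and 0.0697). The fatty acid oxidation call was lost in 5 of 14 fits without single arrays (adjusted p from 0.081 to 0.593) and with quantile normalization or normexp (medians -0.10 and -0.09, adjusted p = 0.196 and 0.106). The red blood cell call was lost without EDL Ts1Cje replicate 2, EDL WT replicate 3 or soleus Ts1Cje replicate 1 (adjusted p from 0.093 to 0.387). The fast fibre median was 0.26 with the slide as a block or without soleus Ts1Cje replicate 1, and the glycolysis median 0.21 with the mean of probes. Without EDL Ts1Cje replicate 2 the medians of oxidative phosphorylation, fatty acid oxidation and red blood cells were -0.05, -0.05 and -0.325. Without EDL WT replicate 2 those of glycolysis and red blood cells were 0.20 and -1.06, and without EDL WT replicate 3 that of red blood cells was -0.27. Without soleus WT replicate 3 those of fatty acid oxidation and glycolysis were -0.08 and 0.07, and without soleus WT replicate 1 that of oxidative phosphorylation was -0.055.

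The mean of both genotype effects, with equal weight to each muscle, called 37 of 14170 genes (limma), of which 33 rose and 4 fell, and 1307 had an unadjusted p under 0.05. Of the trisomic list 21 members rose over all genes and 42 over the list alone, with a median log2 of 0.57 (camera adjusted p = 1.16e-45, and 1.71e-06 with an estimated correlation; Fisher's exact test of the calls, two-sided, p = 1.36e-43). Dnah11 (limma adjusted p = 2.67e-09, log2 4.66 with normexp) and Sod1, by log2 0.97 ± 0.09 (SE, adjusted p = 0.000448), rose. So did Tmem50b by 0.81, Runx1 by 0.89, Eva1c by 0.84, Ifnar2 by 0.73, Vps26c and Synj1 by 0.65 and 0.64, Gart by 0.59, Morc3 by 0.58 (0.35 with normexp) and Son by 0.53. Outside the segment, Mansc1 rose by 0.87, Tpmt, a thiopurine methyltransferase, by 0.73, Rab32 by 0.71 and Dppa5a by 0.70, while Pvalb fell by 0.92 (adjusted p = 0.029) and Vmn2r111 fell by 0.48. Myh4 (-2.05, adjusted p = 0.0685), Dyrk1a (0.85, adjusted p = 0.0512), Rcan1 (0.61, adjusted p = 0.469), Atp6v1e2 (-0.61) and Zfp963 (-0.55) were not called. Dyrk1a was called in 10 of 26 other fits (adjusted p from 0.0206 to 0.0476), Myh4 with normexp, quantile normalization or array weights or without soleus Ts1Cje replicate 2 (adjusted p from 0.00883 to 0.0499), and Atp6v1e2 without EDL WT replicate 3 or soleus Ts1Cje replicate 4 (adjusted p = 0.0111 and 0.0439). App (0.25), Ppargc1a (0.045), Myh2 (0.02) and Tnnt3 (0.00) were not called either. Nor were Atp2a1 (-0.29), Tnnt1 (-0.29), Itsn1 (-0.15), Myh7 (-0.09) and Myh1 (-0.02). Of these 9, all but App and Atp2a1 change direction under other settings or without single arrays. With normexp the calls of Runx1, Mansc1, Eva1c, Tpmt, Rab32, Dppa5a and Vmn2r111 were lost (adjusted p from 0.0716 to 0.534), as were those of Runx1 and Tpmt with the mean of probes (adjusted p = 0.301 and 0.137). With the slide as a block, the calls of Pvalb, Tpmt and Vmn2r111 were lost (adjusted p from 0.0544 to 0.0684). No filter ended the calls of Mansc1, Eva1c, Tpmt, Dppa5a, Pvalb and Vmn2r111 (adjusted p from 0.0639 to 0.12), array weights that of Pvalb and quantile normalization that of Vmn2r111 (adjusted p = 0.0595 and 0.0507). A trended robust variance ended those of Mansc1, Eva1c, Tpmt, Dppa5a and Vmn2r111 (adjusted p from 0.0524 to 0.251). Over 14 fits without single arrays, Pvalb and Vmn2r111 lost the call in 11 each, Eva1c and Tpmt in 10 each, Mansc1 in 5 and Dppa5a in 1 (adjusted p from 0.0508 to 0.104). The calls of the soleus and of the mean shared 22 genes that rose and 2 that fell. Across 14170 genes, which are not independent replicates, the effects in the EDL and the soleus had a Pearson r of 0.312 (jackknife SE 0.218 over arrays) and a Spearman rho of 0.263, 0.725 and 0.727 in the trisomic list.

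In the mean, interferon-stimulated genes had a median log2 change of 0.27, with 32 of 35 higher (camera adjusted p = 8.38e-08, and adjusted p = 0.57 with an estimated correlation), 0 members called over all genes and 7 that rose over the list alone. Heat shock genes had a median of 0.16, with 15 of 15 higher (adjusted p = 0.00335, and adjusted p = 0.57 with an estimated correlation). The fast fibre list had a median of -0.05 (15 of 21 lower, adjusted p = 0.000233, and adjusted p = 0.57 with an estimated correlation), with 1 member that fell over all genes and 3 over the list alone. The matrix list (median 0.18, adjusted p = 0.0364, and adjusted p = 0.671 with an estimated correlation) and the macrophage list (median 0.15, adjusted p = 0.035, and adjusted p = 0.57 with an estimated correlation) were called upward. With the slide as a block both calls were lost (adjusted p = 0.357 and 0.21). Neutrophil markers were lower (median -0.60, 3 of 3, adjusted p = 0.0364, and adjusted p = 0.36 with an estimated correlation). In these last 3 lists and the heat shock list 0 members were called over all genes, and over the list alone 1 neutrophil marker fell. Over 14 fits without single arrays the matrix, macrophage and neutrophil calls were lost in 7 each (adjusted p from 0.0537 to 0.357). The matrix call was also lost under quantile normalization (adjusted p = 0.057), and the macrophage and neutrophil calls with the mean of probes (adjusted p = 0.0535 and 0.0774). With normexp the matrix, heat shock, neutrophil and fast fibre medians were 0.11, 0.10, -0.22 and -0.10, and under quantile normalization the last was -0.10. The fast fibre median was -0.08 without EDL Ts1Cje replicate 1, -0.10 without EDL WT replicate 3, and -0.09 with the slide as a block or without soleus Ts1Cje replicate 1 or soleus WT replicate 4. Without EDL Ts1Cje replicate 3 the heat shock, macrophage and neutrophil medians were 0.10, 0.26 and -0.39. Without EDL WT replicate 3 the macrophage and neutrophil medians were 0.25 and -0.39. The macrophage median was 0.23 without soleus Ts1Cje replicate 4, and the matrix median 0.06 with the slide as a block or without soleus Ts1Cje replicate 1.

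The muscle comparisons asked what separates the EDL from the soleus in each genotype. In WT the genes of slow fibres were lower in the EDL: Myh7 fell by 6.27 ± 1.20 on the log2 scale (SE, 77.2-fold), the slow troponins Tnnc1 and Tnni1 fell by 5.50 and 5.38, and the slow calcium pump Atp2a2 fell by 5.21. Genes of fast fibres were higher, with Pvalb up by log2 3.24 ± 0.23 (SE, 9.47-fold), Actn3 by 3.37 and Myh4 by 2.19 ± 0.57 (SE, limma adjusted p = 0.0126, 0.0536 under quantile normalization and 0.0511 without EDL replicate 2). Of 14170 genes limma called 4142 in WT, of which 2667 rose and 1475 fell, and 4274 in Ts1Cje, of which 2496 rose and 1778 fell (n = 3 EDL and 4 soleus arrays). The calls of both genotypes shared 1999 genes that rose and 1024 that fell, beside 469.8 and 185.1 for independent lists. In Ts1Cje, Myh4 rose by log2 6.36 ± 0.57 (SE), Actn3 by 5.52 and Pvalb by 5.16, and Myh7 fell by 6.79, Tnnc1 fell by 6.50, Tnni1 fell by 6.51 and Atp2a2 fell by 5.99.

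All 18 measured slow fibre genes fell in both genotypes, over all genes and over the list alone, with medians of -4.14 in WT and -5.12 in Ts1Cje (camera adjusted p = 5.2e-17 and 8.95e-17, and adjusted p = 0.139 and 0.154 with an estimated correlation). Others among them were the myosin genes Myl3 (-5.61 and -6.34), Myl2 (-5.18 and -5.94) and Myh7b (-5.56 and -6.45), Tpm3 (-5.09 and -6.01) and Tnnt1 (-4.84 and -5.75), and Sln, the calcium pump regulator sarcolipin, fell by 4.67 and 6.30. Of the fast fibre list 19 of 21 rose and 1 fell in each genotype over all genes, with 19 and 20 that rose over the list alone. Its medians were 1.65 and 1.71 (adjusted p = 7.45e-14 and 6.13e-17), with an adjusted p = 0.0639 in WT with an estimated correlation and 0.0316 in Ts1Cje. Myh2 was the member that fell, by 2.30 in WT and 2.08 in Ts1Cje, and Myh1 was not called at 0.32 and 0.51, which turn to -0.22 and -0.13 under quantile normalization. Atp2a1 rose by 1.65 and 2.24, the fast troponin Tnnt3 by 1.06 and 1.04 (0.675 and 0.53 with normexp, 0.61 and 0.53 under quantile normalization), and the fast myosin-binding protein gene Mybpc2 by 3.41 and 5.15.

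Of 21 glycolysis genes, 19 rose in each genotype, over all genes and over the list alone, with medians of 1.46 and 1.63 (camera adjusted p = 1.17e-16 and 6.13e-17, and 0.0292 and 0.0257 with an estimated correlation). Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase, rose by 2.61 and 2.97, the phosphorylase kinase subunits Phkg1 and Phka1 by 2.47 and 2.43 in WT and by 2.70 and 2.67 in Ts1Cje, Pgm1 by 2.08 in Ts1Cje and Gapdh by 0.87 in WT (0.33 with normexp, 0.35 under quantile normalization). Of 29 fatty acid oxidation genes 20 fell in WT and 22 in Ts1Cje over all genes, and 21 and 23 over the list alone (medians -0.69 and -0.83, adjusted p = 1.55e-10 and 3.24e-12, and adjusted p = 0.289 and 0.209 with an estimated correlation). Fabp3, a fatty acid carrier, fell by 1.55 and 1.79, the fatty acid transporter Cd36 fell by 1.01 and 1.19, Acaa2 fell by 0.96 in WT and Acadl fell by 1.19 in Ts1Cje. Of 20 calcium handling genes 15 rose and 3 fell in each genotype, and 16 and 15 rose over the list alone, with medians of 0.80 and 0.79 (adjusted p = 0.00016 and 0.000138, and adjusted p = 0.124 and 0.119 with an estimated correlation). The calcium store protein Casq2 of slow fibres fell by 2.71 and 3.02, and its fast counterpart Casq1 rose by 1.76 in WT.

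Markers of adipocytes and macrophages were lower in the EDL, and the lists of other cells were not called. Of 12 adipocyte markers 4 fell in WT and 9 in Ts1Cje over all genes, and 10 and 9 over the list alone (medians -1.63 and -1.55, camera adjusted p = 0.00086 and 0.00017, and adjusted p = 0.551 and 0.465 with an estimated correlation). Cidec, a lipid droplet protein, fell by 2.42 and 3.55, Pck1 fell by 2.54 in WT, Adipoq, which encodes adiponectin, fell by 3.17 in Ts1Cje, and Plin1, a lipid droplet coat protein, was at least 4.9-fold lower there. With normexp Cidec stood at -1.16 and -1.96, and Adipoq and Plin1 in Ts1Cje at -1.81 and -1.06, all called. In WT the calls of Cidec and Pck1 were lost in 4 each of 7 fits without single arrays (adjusted p from 0.0508 to 0.158). In Ts1Cje the calls of Adipoq and Plin1 were lost without EDL replicate 1 (adjusted p = 0.0655 and 0.0716). Of 11 macrophage markers 6 and 4 fell over all genes, and 6 and 5 over the list alone (medians -0.51 and -0.57, adjusted p = 0.00202 and 0.0111, and adjusted p = 0.342 and 0.495 with an estimated correlation). The complement genes C1qc (-0.86 and -0.92) and, in WT, C1qa (-0.86) were among them. The call of C1qa was lost in 4 of 7 fits without single arrays (adjusted p from 0.0603 to 0.151). Of 25 matrix genes 6 and 8 fell, over all genes and over the list alone (medians -0.28 and -0.26, adjusted p = 0.000453 and 0.00444, and adjusted p = 0.611 and 0.782 with an estimated correlation). Timp1, an inhibitor of matrix proteases, fell by 3.03 and 2.76 (by 1.79 and 1.78 with normexp), Postn, which encodes periostin, fell by 2.48 and 2.35, and Fn1, which encodes fibronectin, fell by 1.33 in WT. Interferon-stimulated genes had medians of -0.26 and -0.30, with 2 and 3 of 35 that fell, over all genes and over the list alone (adjusted p = 0.01 and 0.00601, and adjusted p = 0.722 and 0.782 with an estimated correlation). With the pairs as a block or under quantile normalization that call was lost in WT (adjusted p = 0.0648 and 0.0668). In Ts1Cje the interferon, matrix and macrophage calls were lost without soleus replicate 1 (adjusted p = 0.147, 0.0927 and 0.0747), and the interferon call without EDL replicate 1 (median -0.13, adjusted p = 0.213). With the slide as a block the medians of the matrix list were -1.04 and -0.85, those of the interferon list -0.81 and -0.72, and that of the macrophage list -1.07 in WT. Without soleus replicate 1 or 4 the matrix median in Ts1Cje was -0.13 or -0.42, and without EDL replicate 2 the adipocyte median in WT was -1.02. With probes well above background on all arrays the adipocyte medians were -0.55 and -0.84. With normexp the medians in WT were -0.64 for adipocytes, -0.43 for the matrix and -0.12 for interferon, and in Ts1Cje -0.29 for macrophages and -0.20 for interferon, and under quantile normalization those of the matrix were -0.46 and -0.41.

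Outside these lists, Mybph, a myosin-binding protein gene, rose by log2 5.85 in WT and 5.71 in Ts1Cje, and Tspan8, a tetraspanin, by 4.22 and 5.42. Cntnap2 was at least 6.86-fold and 11.3-fold higher in the EDL, since it was below background in the soleus (log2 1.05 and 1.27 with normexp). In WT, Gdap1 rose by 3.70, the transcription factor gene Six2 by 3.64 and Sh3kbp1 by 3.48, and Ppm1n was at least 2.7-fold higher, with 2.16, 2.40, 1.60 and 0.61 in turn under normexp. In Ts1Cje, Mss51 rose by 5.32 and Lrtm2 was at least 14.2-fold higher (log2 1.74 with normexp, and Tspan8 3.12). With the slide as a block limma called 1364 genes in WT and 2127 in Ts1Cje, and the Ts1Cje arrays of slide 1 alone (3 EDL against 1 soleus, with the lone array assumed to vary like the other groups) gave 1847. No slide held both muscles of WT, so the slide-block values in WT rest on the 1 soleus array of slide 1, Ts1Cje replicate 1. The slide block ended the WT calls of Myh7, Myl2, Myh2, Myh4, Atp2a1, Gapdh, C1qa, Cidec and Pck1 (adjusted p from 0.0535 to 0.352). Normexp ended the WT calls of Pck1 and C1qa (adjusted p = 0.188 and 0.0628), no filter those of Pck1, C1qa and Cidec, quantile normalization that of Pck1, and the muscles of WT fitted alone those of Pck1 and Cidec (adjusted p from 0.0516 to 0.0818). With probes well above background on all arrays Sh3kbp1 stood at 0.07 in WT (adjusted p = 0.914), and with the mean of probes at 1.77. The slide block also ended the Ts1Cje calls of Mss51, Plin1 and Adipoq (adjusted p from 0.0657 to 0.0847). Within slide 1 the Ts1Cje calls of Myh7 and Myh2 were lost as well (adjusted p = 0.0544 and 0.0601).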

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

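The tests of the slide, of fast muscle left on the samples, of the Dnah11 copy number, of Cdca7l transcripts and of Sod1 copies were chosen after the result was seen, and the test of the number of arrays was written before its fits but after the counts without single arrays were known.

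In the Ts1Cje soleus 3 of 21 fast fibre genes fell, Myh4, Actn3 and Pvalb, and 18 were lower. The slide, or the 1 Ts1Cje soleus array on the other slide, is argued against as the whole cause, since within slide 2 the list was lower and called (median log2 -0.192, camera adjusted p = 1.16e-06) and Myh4, Actn3 and Pvalb stood at -4.27, -1.78 and -1.79, not called with fewer arrays (limma adjusted p = 0.15, 0.15 and 0.0821), though with an estimated correlation the list was called neither there nor over all soleus arrays (camera adjusted p = 0.705 and 0.351). Fast muscle left on the WT samples may contribute and stays open. Outside the fibre, calcium and glycolysis lists, 35 genes were at least 8-fold higher in the EDL than in the Ts1Cje soleus. Of these, 33 were lower in that soleus than in WT (median -0.826, all genes 0.06), a result this choice favours. The share of fast muscle each gene would need had a median of 0.0546. Within a factor of 2 of it lay 71.4%, under the 90% set for a single source. A difference in fibre type by genotype would also lower such genes, and these data do not separate the explanations.

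Dnah11 and Sod1 stood above the ratio of copy numbers. For Dnah11, which lies in a segment known to be deleted rather than gained, a change in copies alone is argued against by the lower bound of 103-fold, the smaller of both muscles, and by log2 4.45 in the EDL with normexp, the lowest value of any setting. Transcripts of Cdca7l, whose probe shares 4 bases with that of Dnah11, are argued against as the source, since that probe was well above background on 0 of 7 Ts1Cje arrays. Sod1 was left off the trisomic list since its extra copy is known not to be functional. The 95% interval of its mean log2 change, 0.77 to 1.17 (1.71-fold to 2.24-fold), argues against 3 copies at the usual level each (0.58). Its mean of 0.97 stood above 51 of 53 list members. An altered promoter or transcript at the ends of the rearranged segments is a hypothesis that probe levels do not test.

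In the soleus 34 genes were called and in the EDL 1, and the difference of the effects called 0. Fits with 3 soleus arrays per genotype called a median of 4 genes (1 to 14 over 16 fits), and 2 of the 16 called at most the EDL count, while at an unadjusted p under 0.05 they had 852 to 2265 genes beside 411 in the EDL. The number of arrays may thus account for part of the gap, while that median stayed over 1.5 times the EDL count and some fits did not, so the explanation stays open. A weaker response of the EDL, the biological explanation, stays open too.

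Other groupings of the same arrays show how often chance gives as much. For the 34 soleus calls the real split alone gave as many (1 of 35, the smallest share possible, highest other 1). The same holds for the 37 calls of the mean (1 of 100, highest other 9). Between muscles it holds in WT (4142 calls, 1 of 35, highest other 499). In Ts1Cje it holds too (4274, 1 of 35, highest other 1156, from the split by slide). It also holds for the trisomic median in the soleus (0.63, highest other 0.37, 1 of 35). Such shares, unadjusted over results, do not exclude chance. Other splits reached the 1837 soleus genes at an unadjusted p under 0.05 (highest other 2002). They also reached the fast fibre median in the soleus (0.16 in size, highest other 0.21, 5 of 35). The same is true of the correlation of both effects (0.31, highest other 0.40 in size, 8 of 100). The fast fibre mean per array had an exact permutation p = 0.0286. In the EDL the 10 splits are too few for a share under 0.05: 1 call against a highest other of 21 (3 of 10 splits as large), and a trisomic median of 0.53 against a highest other of 0.21 (1 of 10). A split that calls 21 genes points to a structure among the EDL arrays, and the splits that, like the real one, part all 3 pairs called at most 1 gene. For the difference of the effects the test is void, since every split reaches 0 calls (100 of 100, highest other 9). A split of the soleus arrays by slide row called 0 genes.

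Of 172 groups of 4 soleus arrays tested for an array far from the rest, 14 had one, beside 8.6 by chance, at 1 in 20. In WT soleus replicate 1 the list means of the muscle atrophy list (0.21), the housekeeping list (-0.19), the Schwann cell and nerve list (-0.56) and the cartilage and bone list (-0.49) stood apart, as did Zcchc3 (-1.39), Gart (0.31) and Il10rb (-0.98, the others from -0.56 to -0.49). In WT soleus replicate 4 the chromosome 12 deletion list (-0.88), the calcium handling list (-0.20) and Dnah11 (-3.66, the others from -5.77 to -5.45) did. Among the Ts1Cje soleus arrays, replicate 2 stood apart in the denervation list (0.59) and in Rcan1 (4.98, the others from 3.88 to 4.00), replicate 3 in the smooth muscle and pericyte list (0.32), and replicate 1 in Dyrk1a (1.29, the others from 1.67 to 1.72).

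The genotype effects of the muscles differed, by a test of the difference with the preset correlation, in the lists of fast fibres (median 0.163), oxidative phosphorylation (-0.11), fatty acid oxidation (-0.158), glycolysis (0.134) and red blood cells (-0.705), and none of the 5 differences was called with an estimated correlation. Among 6665 kept probes without a gene name, which no comparison above uses, limma called 3 for the genotype in the EDL, 8 in the soleus, 10 for the mean of muscles, 1363 between muscles in WT and 1340 in Ts1Cje, and 0 for the difference of the effects. In the trisomic segment lie 18 of these probes, and 0 of them were called for the genotype, with medians of 0.02 in the EDL and -0.24 in the soleus.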

How the results depend on the processing

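The fits of slide 1 and of slide 2 alone and the segment taken by probe position were chosen after the data were seen, normexp was moved from spot means to medians, and the other settings were fixed before. Except where stated, the cause was not tested. Of 143 called gene values, normexp made 50 over 1.5 times smaller, 32 of them still called, with those printed as bounds among them.

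The trisomic medians kept their direction throughout, at 0.34 to 0.55 in the EDL and 0.42 to 0.65 in the soleus, with the low ends from normexp and 0.50 and 0.61 by probe position. The correlation of the effects moved by less than its jackknife SE. Of the genes named by the rule, 6254 of 6987 values over all settings kept their direction and side of the threshold, 598 lost the call, 26 gained it and 109 turned direction, all 109 in genes that were not called. Of 4584 list values 4098 were the same, 74 lost the call, 85 gained it and 327 turned direction, 13 of them in lists printed here and 0 in called lists.

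For the EDL the count of 1 was 3 with normexp, array weights or a trended robust variance, 2 with quantile normalization or no filter, and 0 with probes well above background on all arrays, which removes Dnah11 by construction. It was 1 to 4 without single arrays. Trisomic calls in the EDL were 1 with normexp, array weights or a trended variance. For the soleus the count of 34 was 6 with no filter, 21 with the mean of probes, 1 with the muscle fitted alone (fewer arrays in the fit), 18 with the slide block, and 9 to 27 without single arrays. Its trisomic calls, 18, were 2, 10, 0 and 9 under the first 4 of these settings and 4 to 13 without single arrays. Trisomic calls without single soleus arrays were 9 without Ts1Cje replicate 1 or 4, 5 without Ts1Cje replicate 2 or WT replicate 1, 4 without Ts1Cje replicate 3, 7 without WT replicate 3 and 6 without WT replicate 4. The difference of the effects called 1 gene with normexp and 0 to 1 without single arrays (1 without soleus Ts1Cje replicate 2). The mean called 22 genes at 1.5-fold or more, which is a stricter threshold, and 21 with no filter. Between muscles, WT called 2492 at 1.5-fold or more and 1364 with the slide block, and Ts1Cje 2699, 2127, and 1847 within slide 1, where fewer arrays enter. Without single arrays the mean called 25 to 40 genes, WT 3101 to 3711 and Ts1Cje 2990 to 4160. Without the filter the median of all genes in Ts1Cje moved from 0.01 to 0.14.

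Called lists in the EDL, 5, were 8 with normexp and 1 with an estimated correlation. In the soleus, 6, they were 11 with no filter and 1 with an estimated correlation, for the difference, 5, 0 with an estimated correlation, and for the mean, 7, 11 with no filter and 1 with an estimated correlation. Between muscles, 9 in each genotype, they were 1 in WT and 2 in Ts1Cje with an estimated correlation.

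In the soleus the genotypes share replicate numbers, but same-numbered arrays did not deviate together (correlations -0.12, -0.29, 0.01 and -0.14, with 0 arrays closest to their own number). Of the 5 pairs of both genotypes side by side on slide 2, Ts1Cje with WT, 2 with 1 had 0.43, 3 with 2 had 0.30, 4 with 3 had 0.09, 2 with 2 had -0.29 and 4 with 4 had -0.14. No fit takes neighbours as a block. Ts1Cje EDL and soleus arrays did not either (-0.09, -0.16 and 0.12). With the replicate block the soleus count was 4, its trisomic calls 0 and the count of the mean 5, and the red blood cell and neutrophil lists were called in the soleus (adjusted p = 0.0109 and 0.0272, and adjusted p = 0.658 and 0.643 with an estimated correlation), and the matrix median between muscles in Ts1Cje was -0.42. In the EDL, where the numbers pair, the count was 1 with the replicate block, and in that muscle and in WT between muscles the pairs changed no other printed call than those of 3 lists given with the results and of Musk in WT.

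These values turned direction. Ranges are the lowest and highest without single arrays, and the direction of a list is that of camera. The medians of lists printed here changed sign 25 times, 0 of them in called lists, and in 15 of these the direction of camera did not.

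In the EDL, Myh4 was -0.036 with quantile normalization (range -0.138 to 0.229), and Pvalb -0.021 with normexp and -0.041 with quantile normalization (-0.147 to 0.223). Atp2a1 was -0.045 with normexp and -0.058 with quantile normalization (-0.158 to 0.228). Myh1 was -0.033 with normexp and -0.019 with array weights (-0.123 to 0.192), and Myh2 -0.178 with array weights (-0.485 to 0.643). Tnnt3 was 0.015 with the mean of probes and 0.025 with array weights (-0.091 to 0.134). Itsn1 was -0.047 with normexp (-0.094 to 0.245) and Ppargc1a -0.014 with normexp (-0.27 to 0.204). Ranges that crossed 0 with no other setting were Myh7 (-2.382 to 0.846) and App (-0.049 to 0.192). The fast fibre list was -0.0174 with normexp and -0.0241 with quantile normalization (-0.0566 to 0.169). The slow fibre list (-0.98 to 0.019) and the red blood cell list (-0.613 to 0.119) crossed 0 without single arrays.

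In the soleus, Itsn1 was 0.331 with the mean of probes, and Myh2 0.046 with normexp and 0.004 with quantile normalization. Ranges that crossed 0 were Myh1 (-0.231 to 0.039), Ppargc1a (-0.241 to 0.337) and Tnnt3 (-0.035 to 0.057).

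For the difference of the effects, Dop1b was 0.134 and Tnnt3 0.013 with the mean of probes, Tnnt3 was 0.02 with array weights (range -0.101 to 0.124), Myh2 -0.06 with array weights (-0.398 to 0.73) and Rcan1 0.017 with normexp (-0.227 to 0.318). Ranges that crossed 0 were Dyrk1a (-0.188 to 0.183), Myh1 (-0.004 to 0.311), Myh7 (-2.552 to 0.676) and Ppargc1a (-0.348 to 0.252).

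For the mean, Itsn1 was 0.392 with the mean of probes. Myh2 was -0.04 with the slide block and -0.148 with array weights (range -0.286 to 0.278). Tnnt3 was -0.021 with quantile normalization and -0.002 with the slide block (-0.041 to 0.072). Ranges that crossed 0 were Myh1 (-0.121 to 0.055), Myh7 (-1.106 to 0.508), Ppargc1a (-0.115 to 0.174) and Tnnt1 (-0.711 to 0.017).

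Between muscles, Myh1 was -0.172 and -0.215 in WT and -0.111 and -0.128 in Ts1Cje, with normexp and quantile normalization in turn. The oxidative phosphorylation list was -0.17 and -0.169 in WT under the same settings, and -0.049 to 0.0254 in Ts1Cje without single arrays. With the slide block, medians of opposite sign were 0.036 for heat shock and 0.155 for denervation in WT, and 0.103 for denervation and 0.011 for oxidative phosphorylation in Ts1Cje.

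Fitting the groups alone gives no value for the difference and the mean, and a slide block leaves the EDL values as they are, since its arrays share a slide. Signal over background limits the genes measured: 14170 passed, and 15 of 68 trisomic genes did not.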

Other observations

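The lists and their tests were fixed in advance, and which of them to describe in this part was chosen after the results were seen.

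Members of further muscle lists differed between the EDL and the soleus, beside 4142 of 14170 genes called in WT and 4274 in Ts1Cje, while none of these lists was called with the main settings. Of 15 neuromuscular junction genes, 4 rose and 1 fell in WT and 5 rose and 1 fell in Ts1Cje (the same adjusted over the list alone), while the list was not called (camera adjusted p = 0.308 and 0.438). Ache, the acetylcholinesterase of the synaptic cleft, rose by log2 2.03 ± 0.27 (SE, limma adjusted p = 0.000166) in WT and by 2.85 in Ts1Cje (1.21 and 1.55 with normexp). Chrne, the adult subunit of the acetylcholine receptor, rose by 1.79 and 2.36 (0.88 and 0.995 with normexp), Ufsp1 by 1.82 and 1.79, and the receptor kinase gene Musk fell by 1.29 (0.85 with normexp) and 1.43, a call lost with the slide block in both genotypes and, in WT, with the pairs as a block (adjusted p = 0.0788). It was lost in WT in 5 of 7 fits without single arrays (adjusted p from 0.0555 to 0.142), in Ts1Cje without replicate 2 of either muscle (adjusted p = 0.108 and 0.0565), and without the filter in both genotypes (adjusted p = 0.0783 and 0.0509). Of 15 calcineurin and NFAT genes, 6 rose and 2 fell in WT and 5 rose and 4 fell in Ts1Cje, and over the list alone 6 and 7 rose and 3 and 5 fell (list adjusted p = 0.558 and 0.693). The catalytic subunits Ppp3ca and Ppp3cb rose by 1.19 and 1.20 in WT and by 1.18 and 1.23 in Ts1Cje, the calcineurin regulator Rcan2 fell by 1.37 and 1.76, and Nfatc2 fell by 1.33 and 1.63, calls lost with the slide block in both genotypes for Nfatc2 and in WT for Rcan2. Without EDL replicate 1, Nfatc2 in WT was -0.83 (adjusted p = 0.0817).

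Of 18 satellite cell and myogenesis genes, 2 rose in each genotype and 4 fell in WT and 5 in Ts1Cje (list adjusted p = 0.302 and 0.294), with 2 and 3 that rose and 4 and 5 that fell over the list alone. Pax7, the marker of muscle stem cells, fell by 1.68 in WT, with the call lost under the slide block, and by 0.88 without EDL replicate 1. Normexp and the muscles of WT fitted alone ended that call too (adjusted p = 0.0786 and 0.0577). The list was called downward in Ts1Cje without the filter (adjusted p = 0.0235, and adjusted p = 0.116 with an estimated correlation). Of 18 denervation genes 3 rose and 6 fell in each genotype, and 3 and 4 rose and 6 and 7 fell over the list alone (list adjusted p = 0.302 and 0.438). Of 15 clock genes 3 rose in each genotype, over all genes and over the list alone (list adjusted p = 0.291 and 0.438), and Bhlhe41, a repressor of the clock, rose by 1.54 and 1.79 (0.61 and 0.74 with normexp), calls lost with the slide block. Of 15 heat shock genes 5 fell in each genotype and 2 rose in WT and 1 in Ts1Cje, with 2 that rose and 5 that fell in each over the list alone (list adjusted p = 0.246 and 0.156). That list was called downward under quantile normalization (adjusted p = 0.00375 and 0.00465, and adjusted p = 0.435 and 0.573 with an estimated correlation) and with normexp (adjusted p = 0.00151 and 0.00283, and 0.412 and 0.542). In Ts1Cje it was also called without the filter and without EDL replicate 3 (adjusted p = 0.0235 and 0.0322, and 0.672 and 0.723 with an estimated correlation). Hspa1a, an inducible chaperone, fell by 2.21 and 1.71, calls lost with the slide block. Of 68 oxidative phosphorylation genes 4 rose and 1 fell in WT and 3 rose and 3 fell in Ts1Cje, with 3 and 2 that rose and 1 and 1 that fell over the list alone. That list had medians of 0.09 and -0.03 (adjusted p = 0.435 and 0.51), which were -0.17 and -0.25 under quantile normalization, where it was called downward in both genotypes (adjusted p = 5.15e-06 and 2.65e-09, and adjusted p = 0.435 and 0.322 with an estimated correlation). With normexp it was called downward too (-0.17 and -0.25, adjusted p = 6.4e-07 and 1.43e-10, and adjusted p = 0.386 and 0.192 with an estimated correlation).

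Single genes of other kinds also differed. Nr4a1, an immediate early gene, rose by log2 1.96 in WT and 2.25 in Ts1Cje, the cartilage collagen gene Col9a1 by 2.43 and 4.20 (0.65 and 1.06 with normexp), and the brown adipocyte marker Cidea fell by 2.70 and 2.87.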
